A study of Mus musculus with 28 samples.

How the data were processed

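The data were the intensities of 45101 probe sets on 28 Affymetrix Mouse 430 2.0 arrays, a one-colour oligonucleotide array on which each probe set is a group of short probes for one transcript. Per the labels, the arrays measured medulloblastomas, gliomas and normal brain tissue of mice that carried a Cre recombinase transgene (hGFAP-Cre) and had lost p53, with Rictor either not targeted, heterozygous or deleted, plus 1 wild-type normal brain. The labels' protocols state that tumours were snap frozen, that the tumour content of the pieces was at least 70%, and that RNA was extracted with TRIzol followed by column clean-up and checked by capillary electrophoresis before labelling with biotin. The design text of the series gives 22 medulloblastomas, 6 gliomas and 24 normal brains; 10 medulloblastomas, 6 gliomas and 12 normal brains were analysed here, and the others were not used here.

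The deposited values are intensity on a linear scale, 1 value per probe set and array, and per the submitters' processing notes they were made with MAS5 and GCOS, whose versions are not given in the sources used here. From the values themselves, the mean of each array after trimming 2% at each end lay between 99.98 and 101, so the arrays had been scaled to one trimmed mean. The median intensity per array lay between 18.8 and 27.8. No detection calls were used here, and the number of arrays limits the precision. The ratio of the 3' to the 5' probe sets, which rises when RNA is degraded, was 0.874 to 2.58 for Gapdh and 1.49 to 6.21 for actin. No columns of identical values were found and every column of the table matched 1 sample.

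Probe sets were named through the platform annotation, in which 34958 had exactly 1 gene symbol, 932 had several and 9211, controls included, had none listed. The 64 control probe sets were left out, and no gene was named from a probe set with several symbols. Through the Entrez identifiers, 0 symbols needed an update. The 1-symbol probe sets covered 18194 genes. Each gene was represented by its probe set with the highest mean, and 13931 genes whose mean lay above the 30th percentile of all probe sets (3.88 on the log2 scale) were tested. Among the named genes only Rora had another probe set called in the opposite direction, so Rora is not described. No probe set of its own was assigned to Trp53, which was not analysed here. Values were tested as log2 of the intensity plus a pseudocount of 6.3, the 25th percentile of the table, so that a log2 difference understates the change of a dim gene. All log2 differences in the text are on this scale. No coordinates are given, since the array annotation states no genome build. Gene order along chromosomes was taken from the RefSeq annotation of assembly GRCm38.p6 only to find which genes neighbour each other.

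Samples were grouped by the tissue and genotype in their labels. The 3 tissue comparisons (medulloblastoma against normal brain, glioma against normal brain, medulloblastoma against glioma) came from one limma model over all 28 arrays with tissue and genotype as additive terms. The 1 wild-type array, Z2, had a genotype term of its own. It therefore added nothing to the tissue differences, though means of n = 12 include it. Rictor-null medulloblastomas were compared with p53-null-only and with Rictor-heterozygous ones in a fit of the 10 medulloblastomas, and Rictor-null with Rictor-heterozygous normal brain in a fit of the 12 normal brains. The comparison of the 1 Rictor-null glioma with the 4 heterozygous ones, and the difference between the Rictor effects in medulloblastoma and normal brain, came from a fit of 10 group means over all 28 arrays. In the glioma comparison the lone array was assumed to vary like the other groups. Each fit used lmFit and eBayes with a mean-variance trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called; every adjusted p for a gene in the text is from limma and two-sided. Rictor was also compared by exact two-sided permutation tests. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

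The groups, comparisons, lists, named-gene rule and alternative settings were fixed before the data were examined. Named genes were the 8 largest rises and the 8 largest falls among the called genes of each comparison (genes with clone or predicted names skipped), up to 4 called members of each list with the largest change, and Rictor with the mTOR and AKT components in every genotype comparison. Where fewer than 8 genes were called, the 8 with the smallest p were taken, given as not passing. For a list with fewer than 2 called members, the rule took up to 2 with the highest mean. Genes and arrays outside this rule are named as chosen after their values were seen.

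The 23 lists tested with camera were the SHH pathway, granule neuron lineage, WNT pathway, cell cycle, astrocyte, oligodendrocyte, oligodendrocyte precursor, neural stem cell, mature neuron, forebrain neuron, cerebellum and Purkinje cell, microglia and macrophage, endothelial cell, mesenchymal and mural cell, choroid plexus, p53 targets, mTOR and AKT pathway components, FOXO targets, sterol and fatty acid synthesis, glycolysis and hypoxia, growth factor receptors and ligands, interferon response, and immediate early genes. Of their members and those of 3 further lists, 350 were tested, 23 lay below the filter on dim probe sets and 35 had no probe set of their own. The 3 further lists, lymphocyte, erythroid and sex-linked genes, had fewer than 3 tested members and were not tested as lists. Camera used a preset correlation of 0.01 between genes, and was repeated with a correlation estimated from the data; p-values were adjusted over the 23 lists and 8 comparisons together. List counts are given over all 13931 genes and, where different, adjusted over the list alone. A list score is the mean log2 value of the list's tested members on an array.

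The fits were tested on simulated data in which 200 of the 13931 genes had been changed by 0.5, 1 or 2 on the log2 scale. Noise was drawn independently for each gene and array, with a single SD per gene pooled over the groups of all tissues. Correlation between genes, a spread that differs between tissues and a structure by title prefix were not simulated, so the shares below do not allow for them. Of the unchanged genes, 0 to 10 were called per comparison, with 10 in normal brain. At a change of 2, 97.0% of the changed genes were recovered in medulloblastoma against normal brain, 98.5% in glioma against normal brain and 98.5% in medulloblastoma against glioma. For the same size the share was 74.2% in Rictor-null against p53-null-only medulloblastoma, 60.6% against heterozygous medulloblastoma, 84.8% in normal brain, 51.5% in glioma and 53.0% for the difference between both Rictor effects. At a change of 1 these shares were 74.6%, 53.7%, 62.7%, 8.96%, 2.99%, 34.3%, 5.97% and 16.4% in the same order.

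The alternative settings were quantile normalization, no pseudocount, no filter and a filter at the median, the mean of a gene's probe sets and all probe sets separately, leaving out _x_at probe sets, the title prefix (YZ or YZ2, whose meaning the labels do not state) as a further term and each prefix alone, array weights, no trend, leaving out each replicate, replicate blocks, tissue without genotype, heterozygous arrays alone, all 28 arrays in the genotype fits, and a pooled comparison group. Leaving out 4 sets of arrays with unusual transcripts, the prefix as a term and each left-out array in the list tests, and the replicate block for the difference of both Rictor effects were added after the data were seen. Chance was assessed by regrouping the arrays, with at most 100 regroupings per comparison.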

Results

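Gene expression was measured on 28 arrays: 10 medulloblastomas, 6 gliomas and 12 normal brain tissues of mice. Medulloblastoma is a tumour of the cerebellum and glioma a tumour with features of glial cells. All mice but 1 had lost p53 and carried hGFAP-Cre, a recombinase transgene driven in neural progenitors and glia, and they differed in Rictor, an essential subunit of the kinase complex mTORC2. The medulloblastomas comprised 3 p53-null-only, 2 Rictor-heterozygous and 5 Rictor-null tumours. Among the gliomas 1 was p53-null only, 4 were Rictor-heterozygous and 1 was Rictor-null. The normal brains comprised 5 Rictor-heterozygous, 5 Rictor-null, 1 p53-null-only and 1 wild-type sample. Arrays are named by the code in their labels (A, B, C or Z with a number). The labels do not say that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Across genes, arrays correlated at r = 0.861 to 0.949 among medulloblastomas, 0.897 to 0.938 among gliomas and 0.856 to 0.982 among normal brains. Between tissues the range was 0.805 to 0.890 for medulloblastoma with glioma, 0.662 to 0.874 for medulloblastoma with normal brain and 0.712 to 0.851 for glioma with normal brain. The first principal component held 49.9% of the variance.

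Several arrays carried transcripts of a tissue or brain region that their label does not name, chosen after their values were seen. Gabra6, a receptor subunit of cerebellar granule neurons, had an intensity of 1740 in normal brain B2, 4153 in C5 and 4918 in Z2, and at most 116 in the other normal brains. Normal brain C2 had 275 for Mki67, 176 for Atoh1 and 380 for Mycn. Medulloblastoma C6 had the lowest Atoh1 (37.5) and Gli1 (23.4) of the 10 medulloblastomas and a Gabra6 intensity of 1324. Medulloblastoma B6 had 1638 for Gabra6. Among the gliomas, Gabra6 was 1014 in B7, 675 in B2 and 204 in A4, and 7.3 to 30.2 in the others. Glioma B1 had 2391 for Usp18, an interferon-induced gene. The actin 3' to 5' ratio was 2.55 ± 0.829 (SD, n = 10) in medulloblastoma, 2.23 ± 0.461 (n = 6) in glioma and 3.74 ± 1.42 (n = 12) in normal brain.

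Rictor, the targeted gene, was examined first. Its brightest probe set had a mean intensity of 251 ± 25.9 (SD, n = 3) in p53-null-only medulloblastomas, 269 ± 11.3 (n = 2) in heterozygous ones and 171 ± 63.5 (n = 5) in Rictor-null ones, whose values ran from 68.8 to 235.8. In normal brain it averaged 282 (250.5 to 388.6, n = 5) in heterozygous and 278 ± 95.5 (SD, n = 5) in Rictor-null samples, 272 in the p53-null-only and 580 in the wild-type sample. The 3 normal brains rich in Gabra6 had the highest values (388.6 in B2, 443.9 in C5 and 580 in the wild-type Z2), and the other 9 ran from 213.3 to 272.1. In glioma it was 376 in the p53-null-only tumour, 265 ± 59.6 (n = 4) in heterozygous tumours and 144 in the Rictor-null tumour. The log2 difference between Rictor-null and p53-null-only medulloblastomas was −0.64 (exact two-sided permutation p = 0.125, adjusted over 4 tests p = 0.25, smallest possible p = 0.0179). Against all other medulloblastomas it was −0.68 (exact permutation p = 0.0159, adjusted p = 0.0635), and against heterozygous ones −0.74 (exact permutation p = 0.190, adjusted p = 0.254). In normal brain it was −0.05 (exact permutation p = 0.730, adjusted p = 0.730). None passed after adjustment, so that this probe set did not separate the labelled genotypes in normal brain. Of the other 4 probe sets, all dimmer, 1 averaged 52.8 ± 26.9 (SD, n = 5) in Rictor-null and 28.1 ± 6.89 (n = 5) in heterozygous normal brain, with 95.4 in the Gabra6-rich C5, the direction opposite to the labelled loss (log2 difference 0.69, SE 0.29, limma adjusted p = 0.983 over all probe sets, though the unadjusted value was under 0.05). Another averaged 12.6 ± 6.27 (n = 5) in Rictor-null and 32.0 ± 20.3 (n = 3) in p53-null-only medulloblastomas (−0.96, SE 0.36, limma adjusted p = 0.999, the unadjusted value again under 0.05). The position of the 5 Rictor probe sets relative to the deleted part of the gene is not given in the sources used here, so they are a limited check, and a transcript outside the deleted part can remain. The labels also give the genotype of the mice, and not the share of cells in each piece in which Cre was active.

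The first comparison asked how medulloblastoma differed from normal brain. All 29 tested cell cycle genes, 12 of 16 genes of the Sonic hedgehog (SHH) pathway and 14 of 18 of the cerebellar granule neuron lineage were higher in medulloblastoma, and 15 of 17 mature neuron, all 12 oligodendrocyte and 11 of 14 astrocyte genes were lower. None of these 6 list calls held with an estimated correlation (adjusted p = 0.394 to 0.692). Mki67, a marker of proliferating cells, had an intensity of 1307 ± 531 (SD, n = 10) in medulloblastoma and 39.5 ± 75.7 (n = 12) in normal brain, a log2 difference of 5.63 (SE 0.43, adjusted p = 3.91e-11). Atoh1, the transcription factor of granule neuron precursors, averaged 1019 (37.5 to 1679) in tumours and 21.5 ± 49.0 in normal brain (log2 difference 5.56, SE 0.55, adjusted p = 2.59e-09). Mobp, a myelin protein, averaged 81.9 ± 141 and 1900 ± 1031 (log2 difference −4.98, SE 0.66, adjusted p = 3.10e-07). Of 13931 genes, 8948 differed, 4491 higher and 4457 lower in medulloblastoma, and 4262 of them by more than 2-fold.

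All 29 tested cell cycle genes were higher in medulloblastoma (median log2 difference 4.13, camera adjusted p = 3.44e-19; adjusted p = 0.394 with an estimated correlation). Among the largest rises of all genes were the mitotic genes Bub1 (5.32, SE 0.31), Ube2c (5.42, SE 0.36) and Top2a (5.26, SE 0.37), the ribonucleotide reductase subunit Rrm2 (5.28, SE 0.35) and the G1 kinase Cdk6 (5.51, SE 0.38). Igfbpl1 was higher by 5.20 (SE 0.40). Of the normal brains, C2 had a cell cycle score of 6.83 against 4.84 to 5.34 in the other Rictor-null ones. In the SHH pathway list 12 of 16 members were higher and 4 did not pass (median 2.36, adjusted p = 0.000626, 0.394 estimated). They included Mycn (4.36, SE 0.29), a growth-driving target of the pathway, Sfrp1 (3.78, SE 0.26), the transcription factor Gli2 (3.51, SE 0.34) and the cyclin Ccnd2 (3.03, SE 0.53). Ptch1, the SHH receptor and a pathway target, ranged from 34.2 in medulloblastoma A3 and 42.3 in C5 to 1942. The granule neuron lineage list had 14 of 18 members higher, 1 lower and 3 not passing (median 2.25, adjusted p = 0.000145, 0.584 estimated). Higher ones were Nhlh2 (5.14, SE 0.45), Pax6 (3.22, SE 0.32) and Nhlh1 (3.18, SE 0.23). The medulloblastomas scored 8.04 to 9.22 in this list, and the Gabra6-rich normal brains Z2 and C5, at 8.61 and 8.53, lay within that range; B2 scored 7.41 and the other 9 normal brains 5.34 to 6.73. In the neural stem cell list 8 of 13 were higher, 1 lower and 4 not passing (median 1.08, adjusted p = 0.0491, 0.505 estimated). They included Sox11 (2.99, SE 0.30), Sox4 (2.25, SE 0.22) and the RNA-binding protein Msi1 (2.01, SE 0.14). That list call ended with the title prefix in the fit (adjusted p = 0.0557). It also ended without any 1 of medulloblastomas A3, A6, B4, B6, C1, C2, C5 and C6 or normal brains B1, B6, C1 and C5 (adjusted p = 0.0503 to 0.0685; range over all alternatives 0.0369 to 0.505).

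Mature neuron genes were lower in 15 of 17 cases, with 2 not passing (median −2.66, adjusted p = 1.44e-05; adjusted p = 0.584 with an estimated correlation). The list's largest falls included the calcium-dependent kinase Camk2a (−5.27, SE 0.72) and the GABA-synthesizing enzymes Gad2 (−4.13, SE 0.41) and Gad1 (−3.98, SE 0.52). Other neuronal genes among the largest falls overall were Hpcal4 (−5.39, SE 0.72), the substance P precursor Tac1 (−5.34, SE 0.44), Kalrn (−5.11, SE 0.58), Resp18 (−5.09, SE 0.63) and Stum (−5.00, SE 0.63). Ddn was lower by −5.23 (SE 0.92) and did not pass within the YZ prefix. Forebrain neuron genes were lower in 11 of 14 cases, 3 not passing (median −2.12, adjusted p = 0.00466, 0.728 estimated). Among them were Cck (−4.48, SE 0.59) and Ppp1r1b (−3.41, SE 0.48). In this list the Gabra6-rich normal brains Z2, B2 and C5 scored 4.44, 4.49 and 4.66, within the 4.22 to 5.83 of the medulloblastomas, and the other 9 normal brains 6.82 to 7.91. All 12 oligodendrocyte genes were lower (median −2.38, adjusted p = 5.75e-05, 0.584 estimated). Examples were Mal (−3.56, SE 0.44), Ermn (−3.25, SE 0.46) and Mbp (−3.03, SE 0.40). Astrocyte genes were lower in 11 of 14 cases, with 1 higher and 2 not passing (median −1.43, adjusted p = 0.00664, 0.692 estimated). Lower ones were Gjb6 (−3.83, SE 0.52), Fgfr3 (−2.74, SE 0.32) and Clu (−2.18, SE 0.28).

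In the glycolysis and hypoxia list 12 of 17 members were lower, 1 was higher and 4 did not pass. Adjusted over the list alone 13 were lower (median −0.76, adjusted p = 0.00915, 0.394 estimated). Its members Hk1 (−2.08, SE 0.19) and Hk2 (3.66, SE 0.33), both hexokinases that start glycolysis, went in opposite directions, and Pfkp fell by 2.48 (SE 0.31). Interferon response genes were higher in 8 of 10 cases with 2 not passing, and in 9 adjusted over the list alone (median 1.23, adjusted p = 0.0391, 0.851 estimated). They included Rsad2 (1.92, SE 0.49) and H2-K1 (1.39, SE 0.28). The interferon call ended without medulloblastoma A3 (adjusted p = 0.0522), C1 (0.0537), C2 (0.0558) or C5 (0.0536; range over all alternatives 0.0182 to 0.851). The remaining 13 lists were not called (adjusted p = 0.234 to 0.878). Of 24 mTOR and AKT components 6 were higher, such as Irs1 (2.87, SE 0.23) and Eif4ebp1 (2.51, SE 0.30), and 15 lower, such as Prkca (−2.71, SE 0.26) and Sgk1 (−2.24, SE 0.24), with 3 not passing (adjusted p = 0.234). Among 18 p53 targets 5 were higher, including Eda2r (3.04, SE 0.26), and 5 lower, including Plk2 (−3.27, SE 0.41), so that the list's median (−0.09) and mean (0.16) differed in sign. The counts of higher, lower and not passing members were 4, 2 and 3 of 9 WNT genes, 1, 6 and 8 of 15 oligodendrocyte precursor genes, 2, 2 and 6 of 10 cerebellum and Purkinje cell genes, and 8, 3 and 5 of 16 microglia genes. They were 0, 5 and 7 of 12 endothelial genes (4 lower adjusted over the list alone), 3, 0 and 9 of 12 mesenchymal and mural genes (2 higher adjusted over the list alone), and 1, 3 and 4 of 8 choroid plexus genes. Of 15 FOXO targets 7 were higher, 5 lower and 3 not passing, and of 12 immediate early genes 4, 6 and 2. Sterol synthesis had 4 higher, 5 lower and 12 not passing of 21 (median 0.10, mean −0.12), and growth factors had 3, 5 and 6 of 14. Of the lymphocyte genes, Cd8a was lower (−0.80, SE 0.23, adjusted p = 0.00376) and Ms4a1 did not pass (0.36, SE 0.17). No erythroid gene was tested. The sex-linked Xist (0.93, SE 1.26) and Eif2s3y (0.10, SE 0.95) did not pass.

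Within the YZ arrays 5439 genes were called in medulloblastoma against normal brain, and within the YZ2 arrays 7735. The counts were 8945 without the 3 normal brains rich in Gabra6 (only B2 and C5 affect the difference), 8819 without normal brain C2 and 9058 without medulloblastoma C6.

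**Figure D1:**
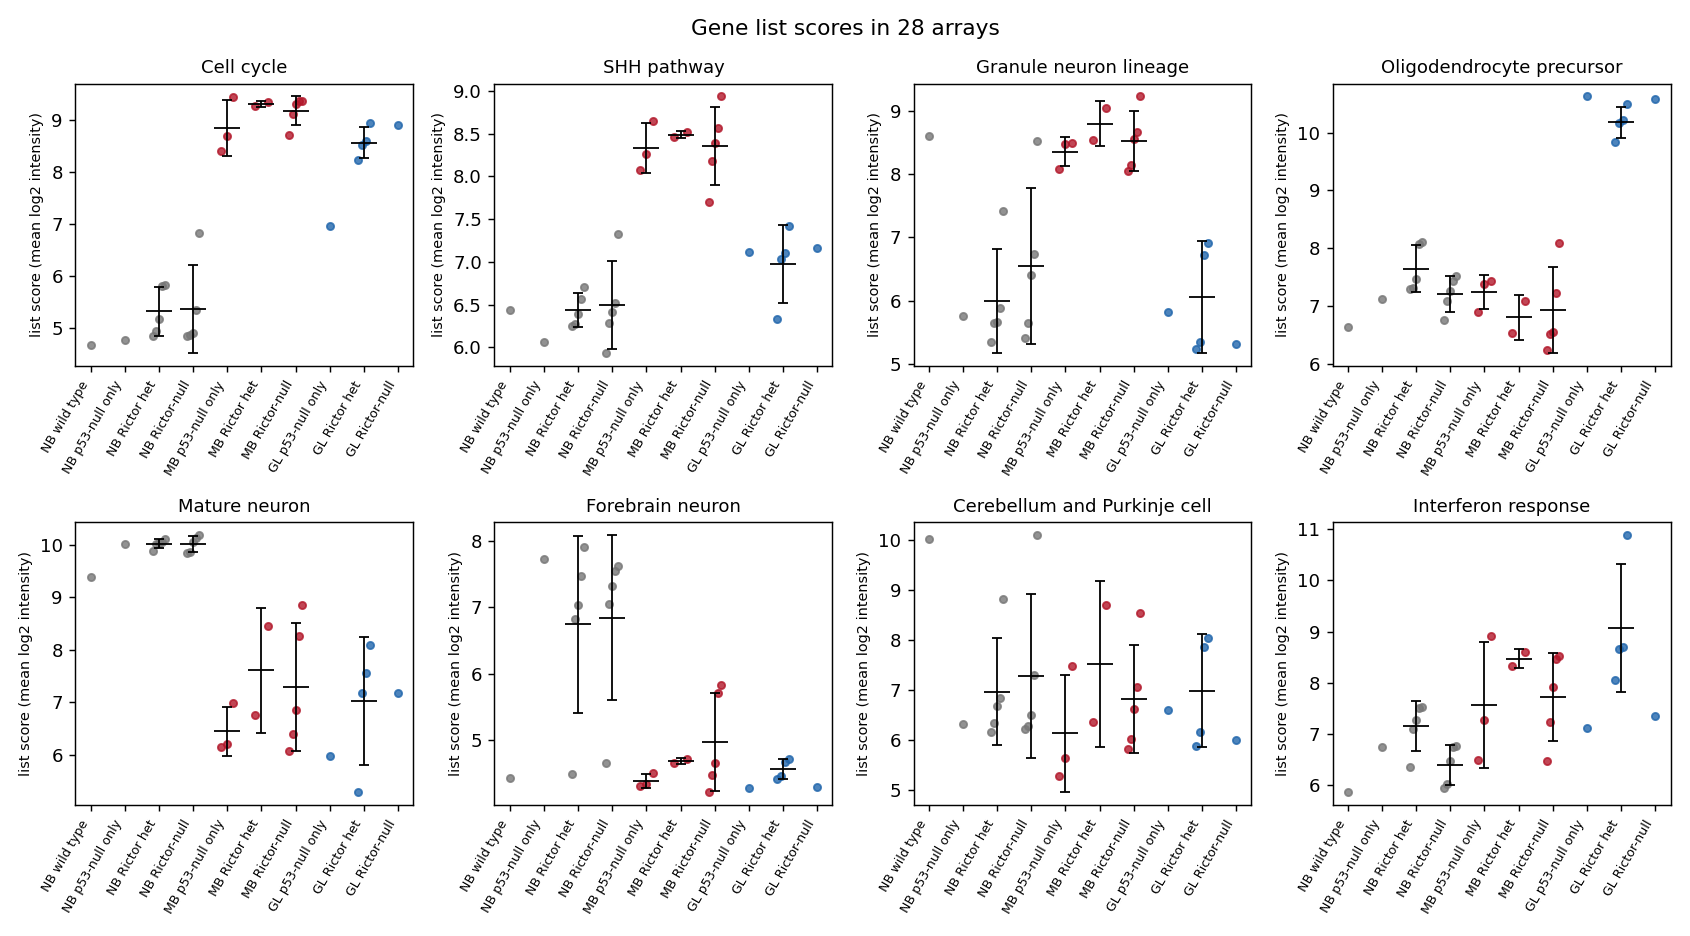
Mean log2(intensity + 6.3) of the tested members of 8 gene lists (vertical axes) on each of the 28 arrays (dots), by the 10 groups of tissue and Rictor genotype (horizontal axes); bars give the mean ± SD of groups with more than 1 array. The cell cycle score of normal brain C2 was 6.83, above the 4.84 to 5.34 of the other Rictor-null normal brains, and the forebrain neuron scores of normal brains Z2, B2 and C5 were 4.44, 4.49 and 4.66, against 6.82 to 7.91 in the other 9.

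The second comparison asked how glioma differed from normal brain. In glioma 14 of 15 oligodendrocyte precursor and 28 of 29 cell cycle genes were higher, and all 17 mature neuron and 12 of 14 forebrain neuron genes were lower. None of these 4 list calls held with an estimated correlation (adjusted p = 0.394 to 0.692). Sox10, a transcription factor of the oligodendrocyte lineage, averaged 1002 ± 127 (SD, n = 6) in glioma and 76.8 ± 39.8 (n = 12) in normal brain (log2 difference 3.57, SE 0.31, adjusted p = 1.32e-09), and Olig2 averaged 1294 ± 254 and 101 ± 61.3 (3.54, SE 0.33, adjusted p = 4.28e-09). Pdgfra, the growth factor receptor of these precursors, averaged 3801 ± 628 and 380 ± 211 (3.23, SE 0.30, adjusted p = 3.22e-09). Of 13931 genes, 7510 differed, 3960 higher and 3550 lower in glioma, 3574 of them by more than 2-fold.

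Oligodendrocyte precursor genes were higher in 14 of 15 cases, with 1 not passing (median 3.23, adjusted p = 2.68e-09; adjusted p = 0.394 with an estimated correlation). They included the matrix proteoglycan Vcan (4.20, SE 0.34) and the transcription factor Nkx2-2 (3.77, SE 0.33). Cell cycle genes were higher in 28 of 29 cases, and in 29 adjusted over the list alone (median 3.20, adjusted p = 2.04e-18, 0.394 estimated). Top2a (4.54, SE 0.42), Mki67 (4.44, SE 0.50), Ube2c (4.41, SE 0.42), Rrm2 (4.22, SE 0.40) and Bub1 (4.17, SE 0.35) were among the 8 largest rises of all genes. So were the collagen Col9a1 (4.66, SE 0.58) and Cdkn2a (4.55, SE 0.78), which encodes the cell cycle inhibitors p16 and p19Arf; Cdkn2a did not pass within the YZ2 prefix, which holds 2 gliomas. Neural stem cell genes were higher in 10 of 13 cases and in 12 adjusted over the list alone (median 1.73, adjusted p = 0.000248, 0.212 estimated). Examples were the radial glial protein Fabp7 (3.10, SE 0.37), Sox4 (2.46, SE 0.25) and Cd44 (1.86, SE 0.41). Interferon response genes were higher in 8 of 10 cases and in 10 adjusted over the list alone (median 1.45, adjusted p = 0.0145, 0.782 estimated). Among them were Usp18 (2.47, SE 0.54) and H2-D1 (1.53, SE 0.30). For Usp18 the glioma values ran from 78.7 to 2391, the latter in B1.

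All 17 mature neuron genes were lower (median −2.78, adjusted p = 3.65e-08; adjusted p = 0.442 with an estimated correlation), including Camk2a (−5.08, SE 0.82), the synaptic vesicle protein Syt1 (−4.29, SE 0.51) and Stmn2 (−4.04, SE 0.42). Forebrain neuron genes were lower in 12 of 14 cases (median −2.48, adjusted p = 0.000688, 0.692 estimated). Examples were Cck (−4.32, SE 0.68), Neurod6 (−4.20, SE 0.63) and the dopamine receptor Drd1 (−3.93, SE 0.74). The gliomas scored 4.29 to 4.72 in this list, and so did the Gabra6-rich normal brains (4.44 to 4.66), whereas the other 9 normal brains scored 6.82 to 7.91. Choroid plexus genes were lower in 6 of 8 cases and in 7 adjusted over the list alone (median −2.37, adjusted p = 0.0168, 0.716 estimated). Ttr, the transthyretin secreted by the choroid plexus, averaged 41.4 ± 53.4 (n = 6) in glioma and 5008 ± 3891 (n = 12) in normal brain (−6.42, SE 1.45, adjusted p = 0.000553), and Clic6 (−3.45, SE 0.69) and Kcnj13 (−2.79, SE 0.61) were lower too. The other large falls were Lamp5 (−5.27, SE 0.70), Hpca (−5.21, SE 0.51), Hpcal4 (−5.14, SE 0.83), Rasgrp1 (−5.07, SE 0.66), Resp18 (−5.04, SE 0.72) and the serotonin receptor Htr2c (−5.02, SE 0.70).

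The other 16 lists were not called in glioma against normal brain (adjusted p = 0.116 to 0.795). In the SHH list 7 of 16 genes were higher, led by Ccnd1 (3.95, SE 0.52; intensity 6052 ± 1565, n = 6, and 570 ± 654, n = 12) and Pdlim3 (3.19, SE 0.50), with 1 lower and 8 not passing. Granule lineage genes were higher in 2 and lower in 3 of 18 (2 and 2 adjusted over the list alone), with Reln lower (−2.39, SE 0.29). The gliomas scored 5.23 to 6.91 in this list, with 6.91 in B7 and 6.72 in B2, the gliomas highest in Gabra6. Of 24 mTOR and AKT components 7 were higher, among them Eif4ebp1 (2.72, SE 0.34), Pik3r1 (1.88, SE 0.24) and Irs1 (1.80, SE 0.27), 5 lower and 12 not passing. Sterol synthesis genes were higher in 8 of 21 cases, and in 7 adjusted over the list alone (adjusted p = 0.116), led by Dhcr7 (2.17, SE 0.35). Of 17 glycolysis and hypoxia genes 7 were lower, including Aldoa (−1.58, SE 0.18) and the glucose transporter Slc2a3 (−1.38, SE 0.13), 1 higher and 9 not passing. Oligodendrocyte genes were lower in 7, higher in 1 and not passing in 4 of 12 cases, and astrocyte genes lower in 4, including Slc1a2 (−1.68, SE 0.31), higher in 1 and not passing in 9 of 14. Of 16 microglia genes 8 were higher and 0 lower. The immediate early list had 6 higher, such as Jun (1.39, SE 0.20), 2 lower, such as Arc (−2.64, SE 0.45), and 4 not passing. Among 15 FOXO targets 4 were higher and 3 lower. Of 18 p53 targets 2 were higher and 4 lower, including Perp (−1.39, SE 0.25), and of 14 growth factor genes 4 were higher, including Erbb3 (2.23, SE 0.36), and 1 lower. WNT genes were higher in 2 and lower in 1 of 9 (2 and 0 adjusted over the list alone), with a median of −0.03 and a mean of 0.38. Cerebellum genes were higher in 1 and lower in 3 of 10 (1 and 2 adjusted over the list alone), endothelial genes in 2 and 4 of 12 and mesenchymal genes in 2 and 3 of 12. Cd8a (−0.45, SE 0.26), Ms4a1 (−0.08, SE 0.20), Xist (0.89, SE 1.44) and Eif2s3y (0.15, SE 1.09) did not pass. Within the YZ arrays 5293 genes were called, and within the YZ2 arrays, with 2 gliomas, 3372. Without glioma B1 the count was 7068, without the 3 normal brains rich in Gabra6 7566, and without normal brain C2 7404.

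The third comparison set both tumour types against each other, since the study concerns opposite roles of Rictor in them. Of the granule neuron lineage genes 13 of 18 were higher in medulloblastoma and 1 lower, of the SHH genes 9 of 16 were higher and 1 lower, and all 15 oligodendrocyte precursor genes were higher in glioma. None of these 3 list calls held with an estimated correlation (adjusted p = 0.121 to 0.394). Nhlh2 averaged 1124 ± 390 (SD, n = 10) in medulloblastoma and 8.27 ± 8.48 (n = 6) in glioma (log2 difference 6.40, SE 0.55, adjusted p = 2.46e-09), and Atoh1 1019 (37.5 to 1679) and 6.92 ± 2.30 (5.92, SE 0.66, adjusted p = 1.75e-07). Gli1, the transcription factor and readout of SHH signalling, averaged 181 ± 98.9 and 5.93 ± 2.45 (3.53, SE 0.42, adjusted p = 3.56e-07). Sox10 averaged 44.4 ± 27.8 and 1002 ± 127 (−4.34, SE 0.33, adjusted p = 4.29e-10). Of 13931 genes, 3959 differed, 1901 higher in medulloblastoma and 2058 higher in glioma, 1734 by more than 2-fold.

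All 15 oligodendrocyte precursor genes were lower in medulloblastoma (median −3.50, adjusted p = 3.44e-19; adjusted p = 0.121 with an estimated correlation), including Gpr17 (−4.38, SE 0.64), Nkx2-2 (−4.15, SE 0.35) and Pcdh15 (−3.86, SE 0.30). Granule lineage genes were higher in 13 of 18 cases, lower in 1 and not passing in 4 (median 2.79, adjusted p = 3.34e-10, 0.394 estimated). Reln was at 3.63 (SE 0.30). SHH genes were higher in 9 of 16 and lower in 1, and in 2 adjusted over the list alone (median 1.07, adjusted p = 0.000660, 0.394 estimated). Sfrp1 (5.31, SE 0.31), Gli2 (3.81, SE 0.41) and Mycn (3.47, SE 0.35) were higher. Cell cycle genes were higher in 13 of 29 cases, and in 22 adjusted over the list alone (median 0.91, adjusted p = 9.81e-06, 0.716 estimated). Among them was Mcm6 (1.82, SE 0.35), which did not pass within the YZ2 prefix. Oligodendrocyte genes were lower in 6 of 12 (median −1.41, adjusted p = 0.000203, 0.584 estimated). Examples were Ugt8a (−3.10, SE 0.31), Cnp (−3.04, SE 0.43) and Cldn11 (−2.43, SE 0.32). Astrocyte genes were lower in 6 of 14, and adjusted over the list alone 8 were lower and 1 higher (median −1.05, adjusted p = 0.0188, 0.765 estimated). Among them was Fgfr3 (−2.53, SE 0.39).

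Of the 24 mTOR and AKT components 7 were lower in medulloblastoma than in glioma, 1 was higher and 16 did not pass (median −0.20, adjusted p = 0.0326; adjusted p = 0.394 with an estimated correlation). Pik3r1, the regulatory subunit of PI3 kinase, averaged 209 ± 72.8 (n = 10) in medulloblastoma and 2006 ± 611 (n = 6) in glioma (−3.18, SE 0.26, adjusted p = 9.35e-10), and the AGC kinases Sgk1 (−2.32, SE 0.30) and Prkca (−2.31, SE 0.32) were lower. The list call ended without glioma A4 (adjusted p = 0.0515) or medulloblastoma A3 (0.0522; range over all alternatives 0.0255 to 0.394). Sterol synthesis genes were lower in 7 of 21 cases (median −0.27, adjusted p = 0.00664, 0.692 estimated). They included Scd2 (−1.23, SE 0.17) and Dhcr7 (−2.35, SE 0.37), the latter not passing among heterozygous arrays alone. The sterol list call ended without glioma A4 (adjusted p = 0.0751, range 0.00190 to 0.692).

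The remaining large differences were the neural transcription factor Insm1 (5.82, SE 0.50), Cdk6 (5.28, SE 0.46), Tbata (5.04, SE 0.53), Mab21l1 (4.82, SE 0.58) and Cyp11a1 (4.66, SE 0.66), higher in medulloblastoma, and Rlbp1 (−4.72, SE 0.62), Kctd4 (−4.41, SE 0.49), the matrix protein Tnr (−4.24, SE 0.43), Susd5 (−4.21, SE 0.29) and Scrg1 (−4.00, SE 0.27), higher in glioma. The choroid plexus list had 2 of 8 members higher and the mesenchymal list 2 of 12 (0 adjusted over the list alone), the endothelial list 2 of 12 lower and the glycolysis list 2 higher and 6 lower of 17 (8 lower adjusted over the list alone). In the 15 lists not called (adjusted p = 0.101 to 0.819) Sox2 (−2.02, SE 0.16), Id3 (−2.44, SE 0.24), Erbb3 (−3.41, SE 0.38), Nr4a1 (−3.25, SE 0.36) and Klf15 (−2.22, SE 0.26) were higher in glioma. Otx2 (4.46, SE 0.77), Neurod6 (4.06, SE 0.67), Stmn2 (3.63, SE 0.44), Hk2 (2.87, SE 0.40), Nkd1 (2.63, SE 0.36), Eda2r (2.63, SE 0.32) and Cited2 (1.99, SE 0.29) were higher in medulloblastoma. Of 18 p53 targets 6 were higher and 4 lower (7 and 4 adjusted over the list alone), and of 15 FOXO targets 6 and 6 (7 and 6). No interferon response gene of 10 passed, and of 16 microglia genes 1 was lower. Cd8a (−0.35, SE 0.28), Ms4a1 (0.44, SE 0.21), Xist (0.04, SE 1.52) and Eif2s3y (−0.05, SE 1.16) did not pass. The median and mean differed in sign for the WNT (−0.09 and 0.27), mature neuron (−0.15 and 0.35), forebrain neuron (−0.18 and 0.23) and FOXO lists (−0.09 and 0.09). Within the YZ arrays 1873 genes were called and within the YZ2 arrays 1119. The count was 4250 without medulloblastoma C6 and 3899 without glioma B1.

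**Figure D2:**
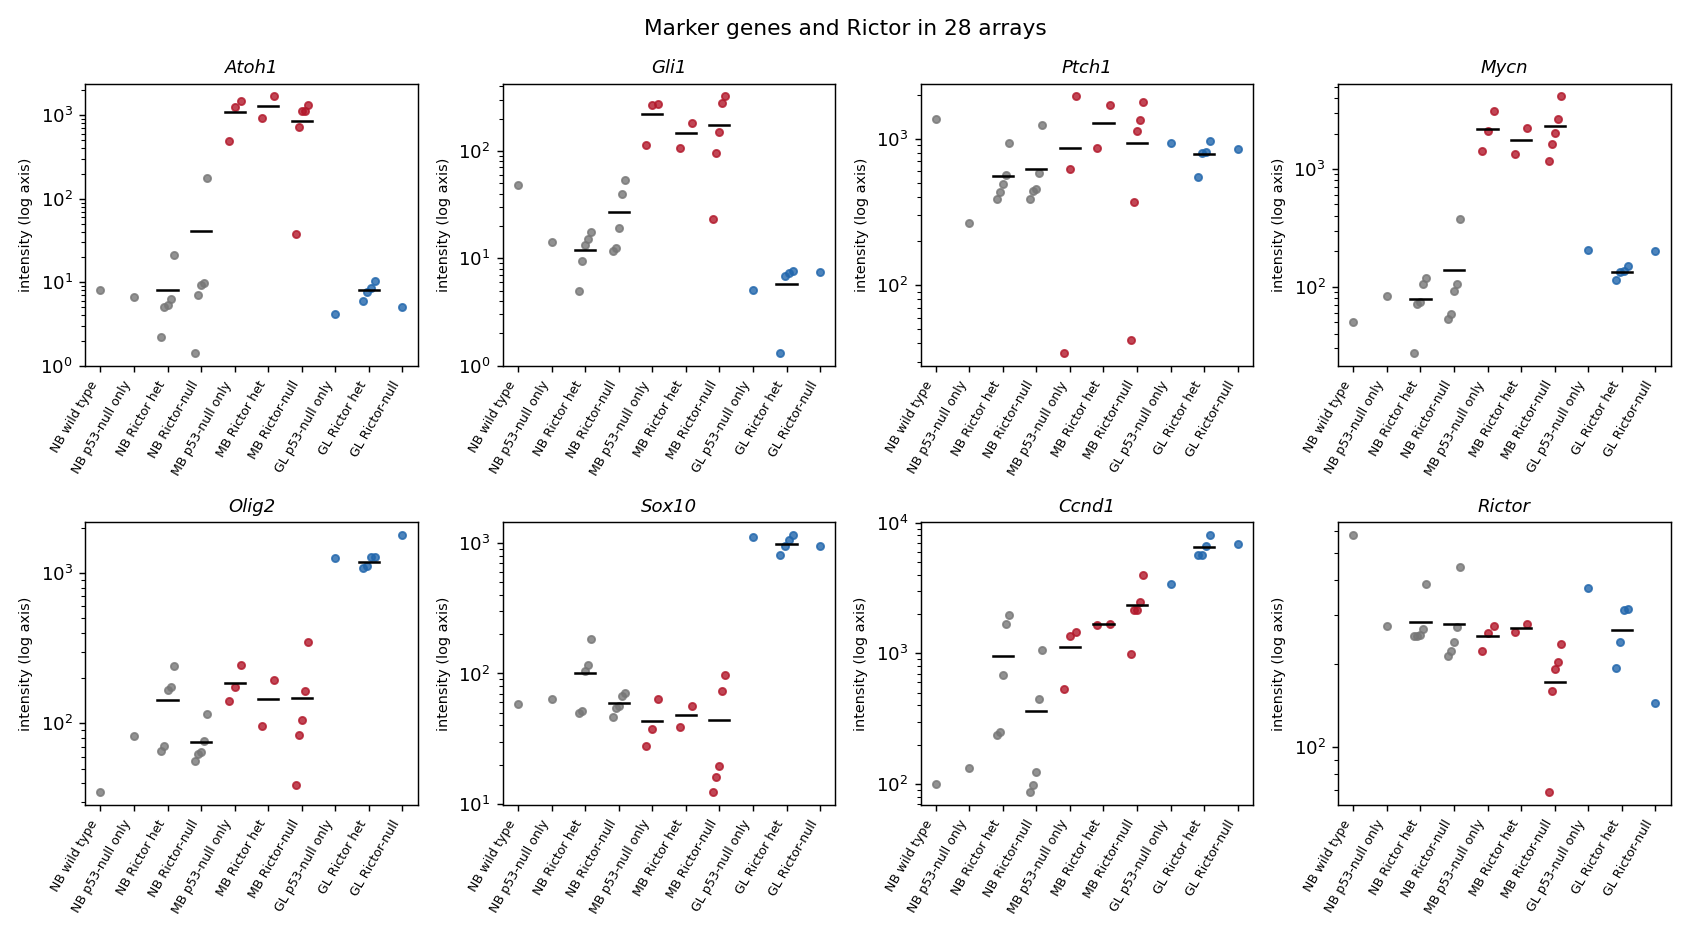
Intensity (vertical axes, logarithmic) of Atoh1, Gli1, Ptch1, Mycn, Olig2, Sox10, Ccnd1 and Rictor on each array (dots), by the 10 groups of tissue and Rictor genotype (horizontal axes); lines give group means. Atoh1 averaged 1019 in medulloblastoma and 6.92 in glioma, Sox10 44.4 and 1002, and Rictor 171 in Rictor-null medulloblastomas and 278 in Rictor-null normal brains.

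The next comparison asked what differed between Rictor-null (n = 5) and p53-null-only (n = 3) medulloblastomas. The gene Tmem267 was the one called: it averaged 97.5 ± 22.4 (SD, n = 5) in Rictor-null and 8.10 ± 5.95 (n = 3) in p53-null-only tumours, a log2 difference of 2.91 (SE 0.33, adjusted p = 0.0234), with all 5 Rictor-null values (72.6 to 131.5) above all 3 others (2.1 to 14). The 2 heterozygous tumours had 92.7 and 118.8. The call of Tmem267 ended without p53-null-only A3 (adjusted p = 0.205) or A5 (0.124), and without Rictor-null C1 (0.117), C2 (0.0540) or C5 (0.128). It also ended with no pseudocount (0.0608, with 1 other gene called), with the title prefix in the fit (0.0788), within the YZ arrays (0.550) and with the heterozygous tumours pooled in (0.999). Over 21 alternatives its adjusted p ran from 3.45e-06 to 0.999, and the count of genes from 0 to 6; it was 3 without Rictor-null C4 or without C6, and 0 among the YZ arrays alone. At an unadjusted p under 0.05, limma gave 605 genes, less than the share of 0.05 of all tested genes that chance alone gives. In every other Rictor comparison the count at this limit was below that share too. The genes next in rank did not pass. Fgf5 averaged 26.2 ± 7.58 in Rictor-null and 294 ± 208 in p53-null-only tumours (−3.02, SE 0.50, adjusted p = 0.284). Igfbpl1 averaged 275 ± 71.9 and 947 ± 196 (−1.77, SE 0.30, adjusted p = 0.284), and the interferon-inducible Ifi202b 38.4 ± 20.8 and 0.400 ± 0.173 (2.58, SE 0.42, adjusted p = 0.284). Heterozygous B4 and B6 had 77.3 and 13.3 for Fgf5, 392.9 and 181.4 for Igfbpl1 and 116 and 96.8 for Ifi202b. All lay nearer the Rictor-null mean. Lgals7 (1.71, SE 0.32), Spata5l1 (1.52, SE 0.29), Tmem87a (−2.31, SE 0.44) and Npas3 (−1.52, SE 0.30) had adjusted p = 0.435 to 0.468.

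No member of any list passed over all genes in Rictor-null against p53-null-only medulloblastomas, while 12 of 23 lists were called as groups and 0 with an estimated correlation. The list medians were higher in Rictor-null tumours for cell cycle (0.29, adjusted p = 0.00122; adjusted p = 0.851 with an estimated correlation), mature neuron (1.01, adjusted p = 0.00915; 0.862 estimated), forebrain neuron (0.76, adjusted p = 0.0113; 0.700 estimated) and oligodendrocyte genes (0.47, adjusted p = 0.0391; 0.862 estimated). Adjusted over the list alone, 1 mature neuron gene passed and went against its list, the glutamate transporter gene Slc17a6 (−1.72, SE 0.37, adjusted p over all genes = 0.570), and 1 forebrain neuron gene was higher, Tbr1 (1.44, SE 0.36, adjusted p over all genes = 0.776); both are named after their values were seen. The medians were lower for neural stem cell (−0.41, adjusted p = 0.000100; 0.394 estimated), FOXO target (−0.46, adjusted p = 0.00140; 0.394 estimated), immediate early (−0.42, adjusted p = 0.00168; 0.579 estimated), endothelial (−0.31, adjusted p = 0.00382; 0.620 estimated) and microglia genes (−0.25, adjusted p = 0.00466; 0.692 estimated). They were also lower for choroid plexus (−1.01, adjusted p = 0.00663; 0.692 estimated), astrocyte (−0.37, adjusted p = 0.00792; 0.781 estimated) and oligodendrocyte precursor genes (−0.42, adjusted p = 0.0404; 0.851 estimated). Of these 12 lists, the neural stem cell and endothelial lists kept their call with any 1 of the 8 arrays left out, and 10 lost it. The astrocyte call ended without p53-null-only A6 (adjusted p = 0.916, mean difference 0.08 in place of −0.41, test downward) or Rictor-null C2 (0.130). The cell cycle call ended without A3 (0.686, mean 0.11 in place of 0.33) or A6 (0.0762), and the choroid plexus call without A5, the tumour with 5340 for Ttr (0.680, mean −0.38 in place of −1.26). The FOXO target (0.0770) and immediate early calls (0.237) ended without A6 and the microglia call without A3 (0.157). The mature neuron call ended without C6, the tumour with 1324 for Gabra6 (0.289), A5 (0.134), A3 (0.0767) or C1 (0.0721), and the forebrain neuron call without C6 (0.0923), C1 (0.0792) or A3 (0.0690). The oligodendrocyte call ended without C6 (0.367), A5 (0.335), C1 (0.0570) or A3 (0.0558) and with quantile normalization (0.0688). The oligodendrocyte precursor call ended without C6 (0.387), A6 (0.181), A3 (0.157), C5 (0.151) or C2 (0.143) and with the title prefix in the fit (0.0697). Over all alternatives the adjusted p of the 12 lists ran from 5.77e-11 to 0.916. Without A5 the mean differences grew for cell cycle (0.63), astrocyte (−0.72), immediate early (−0.77), neural stem cell (−0.73) and oligodendrocyte precursor genes (−0.48). Without A3 that of choroid plexus was −1.92, without C4 those of endothelial and oligodendrocyte precursor genes were −0.43 and −0.60, and without C6 that of endothelial genes was −0.17. The number of called lists was 7 without A3.

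The other 11 lists were not called in this comparison (adjusted p = 0.0507 to 0.878). For the SHH pathway the median was 0.13 and the test pointed down (adjusted p = 0.775), with Ccnd1 at 2343 ± 1063 and 1118 ± 510 (1.07, SE 0.42, adjusted p = 0.981) and Ccnd2 at 0.27 (SE 0.75). WNT (median −0.06, mean 0.04) and glycolysis genes (median 0.11, test down) also differed in sign between these measures. None of the 24 tested mTOR and AKT components passed: Akt1 differed by −0.52 (SE 0.25), Akt2 by 0.52 (SE 0.31), Mtor by 0.04 (SE 0.32), Mapkap1, a subunit of mTORC2, by 0.38 (SE 0.22), and Rptor, a subunit of mTORC1, by 0.35 (SE 0.25). Pik3r1 differed by −0.60 (SE 0.35) and Foxo3 by −0.39 (SE 0.35). Xist was 18.9 in p53-null-only A6 and 21.2 in Rictor-null C6 and 3411 to 6171 in the other 6 tumours.

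Against the 2 heterozygous medulloblastomas, the 5 Rictor-null ones differed in the call of 1 gene. Cxcl13, a chemokine that attracts B cells, averaged 24.5 ± 9.58 (SD, n = 5) in Rictor-null and 328 ± 117 (n = 2) in heterozygous tumours (−3.46, SE 0.39, adjusted p = 0.0219), with all 5 Rictor-null values under both heterozygous ones. The p53-null-only tumours had 4.0 to 8.4. The call ended without heterozygous B4 (adjusted p = 0.238) or B6 (0.182) and without Rictor-null C1 (0.0651), C2 (0.0858) or C4 (0.0593). It also ended with all 28 arrays in the fit (1), with no pseudocount (0.201), with the title prefix in the fit (0.268) and within the YZ2 arrays (1); over 19 alternatives its adjusted p ran from 0.00370 to 1. With B6, C1, C2 or C4 left out the count was 0, without B4 it was 1 other gene, higher in Rictor-null tumours, and limma gave 199 genes at an unadjusted p under 0.05. Skor1 (−3.02, SE 0.51, adjusted p = 0.521) and Zfhx4 (−3.24), Dusp4 (−1.84), Maf (−1.43) and Ly86 (−1.26) did not pass. Of 23 lists 7 were called, all lower in Rictor-null tumours, and 0 with an estimated correlation: microglia (median −0.68, adjusted p = 1.43e-14; 0.394 estimated), choroid plexus (−1.51, adjusted p = 1.96e-05; 0.468 estimated), interferon response (−0.76, adjusted p = 0.000707; 0.692 estimated), oligodendrocyte (−0.55, adjusted p = 0.0161; 0.851 estimated), neural stem cell (−0.16, adjusted p = 0.0241; 0.584 estimated), endothelial (−0.29, adjusted p = 0.0468; 0.765 estimated) and cerebellum and Purkinje cell genes (−0.64, adjusted p = 0.0490; 0.851 estimated). With the title prefix in the fit 4 lists were called, and the interferon (adjusted p = 0.348), oligodendrocyte (0.313), neural stem cell (0.0664) and cerebellum lists (0.305) were no longer among them. The microglia list alone kept its call with any 1 array left out (mean −0.44 in place of −0.73 without heterozygous B4). Choroid plexus genes rested on B4: without it the mean difference was −0.07 in place of −1.83 (adjusted p = 0.912, test upward), and without B6 it was −3.58. The oligodendrocyte and cerebellum directions rested on B6, the tumour with 1638 for Gabra6. Without it the mean differences turned to 0.49 (adjusted p = 0.0235) and 0.46 (0.612), and without B4 they were −1.45 and −1.87. The oligodendrocyte call also ended without Rictor-null C2 (0.0781) or C5 (0.0959), and the cerebellum call without C1 (0.278), C2 (0.0805), C4 (0.167) or C5 (0.0568); without C6 the cerebellum mean was −1.14. The endothelial call ended without B6 (0.580), C1 (0.179), C2 (0.0867) or C6 (0.360) and with quantile normalization (0.0921), and its mean was −0.37 without B4 or C4. The neural stem cell call ended without B4 (0.528), C1 (0.0605) or C6 (0.0784), with a mean of −0.40 without B6, and the interferon call without B4 (0.0637), with a mean of −0.44 without C4. Over all alternatives the adjusted p of the 7 lists ran from 1.11e-17 to 0.912. The other 16 lists had adjusted p = 0.0542 to 0.977, and no mTOR or AKT component passed (Mapkap1 0.44, Prr5l −0.74); that list (median 0.08, mean −0.03) and the FOXO list (0.02 and −0.13) differed in sign between median and mean. Both heterozygous tumours carry the YZ2 prefix. Ttr was 8734 in heterozygous B4 and 18.4 in B6.

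In normal brain, Rictor-null (n = 5) and heterozygous samples (n = 5) differed in 0 genes by limma, with 439 genes at an unadjusted p under 0.05. That count is below the share of 0.05 that chance alone gives. The genes with the smallest p did not pass (smallest limma adjusted p = 0.9997), and no theme among them was tested. Of these, Bst2 averaged 22.6 ± 11.2 (SD, n = 5) in Rictor-null and 55.8 ± 18.4 (n = 5) in heterozygous brain (−1.13, SE 0.28). Lcn2, an iron-binding protein of inflammation, averaged 4.56 ± 5.12 and 44.9 ± 33.0 (−2.04, SE 0.50). Xaf1 differed by −0.86 (SE 0.19), Wipf1 by −0.67, Lrg1 by −0.90, Ctla2a by −1.03 and Lce1h by 1.49. Of 23 lists 9 were called, and 0 with an estimated correlation. The interferon response list was lower in Rictor-null brain (median −0.73, adjusted p = 3.78e-11, 0.394 estimated). Adjusted over the list alone 5 of 10 members were lower, and 0 over all genes. Of the oligodendrocyte genes 1, Mal (−0.82, SE 0.22), was lower adjusted over the list alone. Medians were also lower for oligodendrocyte precursor (−0.44, adjusted p = 5.12e-07; 0.505 estimated), microglia (−0.42, adjusted p = 1.15e-06; 0.620 estimated), oligodendrocyte (−0.53, adjusted p = 3.00e-06; 0.584 estimated) and astrocyte genes (−0.22, adjusted p = 3.13e-05; 0.584 estimated). So were those for endothelial (−0.27, adjusted p = 5.76e-05; 0.620 estimated), neural stem cell (−0.22, adjusted p = 0.00664; 0.399 estimated) and immediate early genes (−0.26, adjusted p = 0.0491; 0.851 estimated). Granule lineage genes had a higher median (0.56, adjusted p = 0.00447; 0.823 estimated), which rested on the Gabra6-rich C5: without it the mean difference was 0.06 in place of 0.55 (adjusted p = 0.731). That call also ended without heterozygous B1 (0.0613; range 2.34e-05 to 0.823), and the mean was 0.91 without B2 and 0.84 without C1. The microglia mean was −0.17 in place of −0.39 without C5, and the astrocyte mean −0.18 in place of −0.33 without the Gabra6-rich B2. The endothelial mean was −0.19 in place of −0.33 without B2 or C1, and the oligodendrocyte mean −0.30 in place of −0.52 without C2. These 4 lists and the interferon, oligodendrocyte precursor and neural stem cell lists kept their call with any 1 array left out. Heterozygous B4 and B7 scored 8.11 and 8.07 for oligodendrocyte precursor genes (other normal brains at most 7.52) and were not left out together. The immediate early call ended with quantile normalization (adjusted p = 0.0694), with the title prefix in the fit (0.105) and without B1 (0.165), B4 (0.192), B6 (0.0637), B7 (0.136), C1 (0.434), C5 (0.316) or C6 (0.125; range 0.000413 to 0.851). Its mean difference of −0.26 ran from −0.46 without C3 to −0.11 without C1, with −0.42 without B2 and −0.13 without C5. The other 14 lists had adjusted p = 0.0542 to 0.848. With the title prefix in the fit the count of genes was 0 as well, and without Rictor-null C6 it was 1. No mTOR or AKT component passed.

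The only Rictor-null glioma, C3, was set against the 4 heterozygous gliomas with the spread taken from all groups. With 1 array the comparison describes this tumour and does not separate its genotype from other features of it. Aen had an intensity of 1420 in C3 and 62.2 ± 14.1 (SD, n = 4) in the others (log2 difference 4.40, SE 0.57, adjusted p = 0.00151), Mrpl46 817 and 149 (129.2 to 176.7; 2.42, SE 0.35, adjusted p = 0.00414) and Mrps11 730 and 113 ± 34.2 (2.69, SE 0.47, adjusted p = 0.0408). Aen encodes a p53-induced nuclease, and both others are proteins of the mitochondrial ribosome. These 3 genes, all higher, were the ones called; 637 had an unadjusted p under 0.05. The call of Mrps11 ended without B3 (adjusted p = 0.0763) and in 5 further alternatives (range over 17 alternatives 0.000633 to 0.249). The count was 8 without B2 and 14 without B7 (87.5% and 78.6% higher). With no pseudocount it was 24, the 3 genes among them, of which 16.7% were higher in C3, so that most of those calls went the other way. In the gene order of the RefSeq annotation of GRCm38.p6 the 3 genes are neighbours. A window of 7 successive genes that holds them (Akap13, AU020206, Klhl25, Ntrk3, Mrpl46, Mrps11 and Aen) averaged 2.62 above the median of the other gliomas in C3 on the log2 scale, while normal brain C3, with the same code, averaged 0.23 above the median of the other normal brains over the same genes. Over this window the highest of the other gliomas averaged 1.94 above the median of the rest. Of 23 lists 3 were called and 0 with an estimated correlation: interferon response lower (median −2.32, adjusted p = 4.49e-05; 0.584 estimated), cell cycle higher (0.34, adjusted p = 0.00721; 0.877 estimated) and endothelial lower (−0.37, adjusted p = 0.0491; 0.782 estimated). Adjusted over the list alone, 1 interferon gene, Ifit3 (−2.61, SE 0.83), was lower and 1 astrocyte gene, Sox9 (1.91, SE 0.51), higher, and neither passed over all genes. Without B1, the glioma with 2391 for Usp18, the mean interferon difference was −1.12 in place of −1.73 (adjusted p = 0.00924; range 2.86e-06 to 0.584) and 9 lists were called; without B3, 6 were. The cell cycle call ended without B2 (0.0997; range 0.00105 to 0.877). The endothelial call ended with quantile normalization (adjusted p = 0.0629), without medulloblastoma C6 (0.0520) and without glioma B2 (0.240) or B7 (0.0515; range 0.00605 to 0.782). Among p53 targets Aen was higher and 17 of 18 did not pass, with a median of −0.34 and a mean of 0.05. No mTOR or AKT component passed, and the median (0.01) and mean (−0.05) of that list differed in sign, as did those of the neural stem cell list (−0.08 and 0.06). The other 20 lists had adjusted p = 0.0716 to 0.977.

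**Figure D3:**
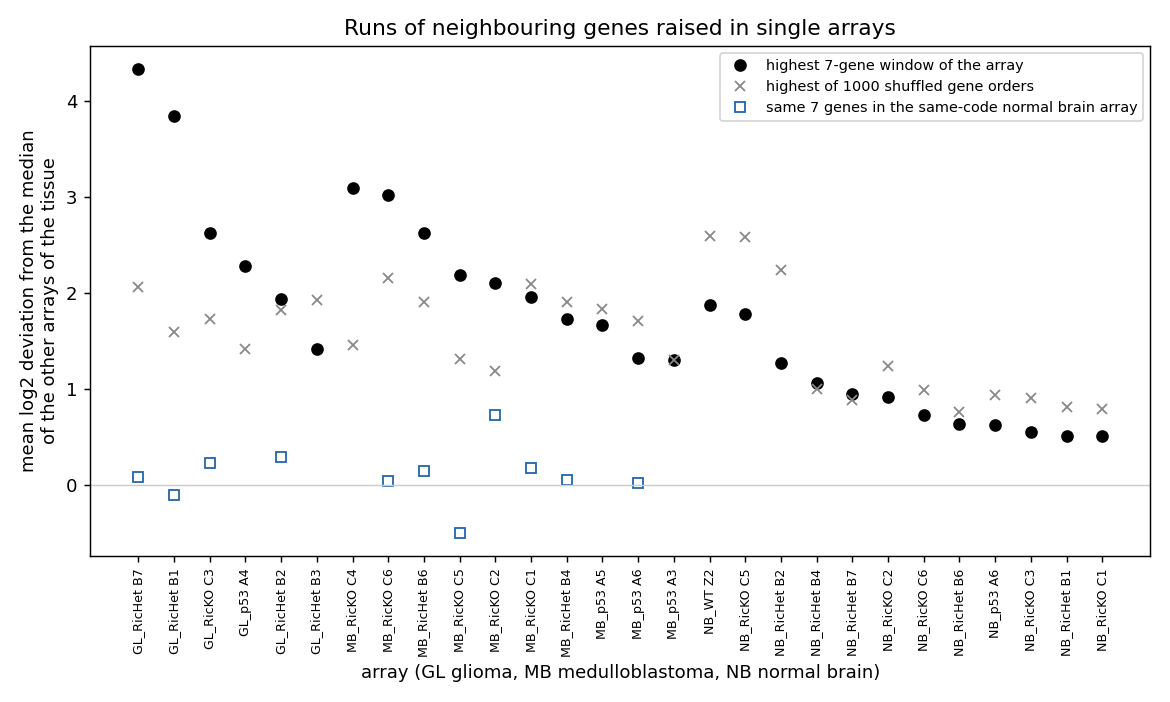
For each array, the highest mean log2 difference from the median of the other arrays of its tissue over 7 neighbouring genes (vertical axis, black dots; arrays on the horizontal axis), the highest value in 1000 shuffled gene orders (crosses), and the value of the same 7 genes on the normal brain array with the same code (blue squares). Glioma B7 reached 4.33 and Rictor-null glioma C3 2.62, whereas the highest normal brain value was 1.88.

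Whether Rictor loss acted differently in medulloblastoma and normal brain was tested as the difference between both Rictor-null against heterozygous effects. No gene passed by limma (264 at an unadjusted p under 0.05; 4 without heterozygous medulloblastoma B4). The smallest p was that of Nectin4 (1.15, adjusted p = 1). For 5 of 23 lists the effects differed, and for 0 with an estimated correlation. The difference was lower in medulloblastoma for choroid plexus (median −2.02, adjusted p = 3.00e-06; 0.394 estimated), granule lineage (−0.57, adjusted p = 0.00416; 0.692 estimated), microglia (−0.35, adjusted p = 0.0259; 0.862 estimated) and cerebellum genes (−0.88, adjusted p = 0.0475; 0.782 estimated), and higher for oligodendrocyte precursor genes (0.57, adjusted p = 0.00174; 0.674 estimated). Each of the 5 lost its call without at least 1 array. Choroid plexus genes rested on heterozygous medulloblastoma B4 (score 8.20, against 4.69 in B6): without it the mean difference was −0.50 in place of −2.25 (adjusted p = 0.520; range 3.08e-11 to 0.520), and without B6 it was −4.01. Granule lineage genes rested on normal brain C5: without it the mean was −0.32 in place of −0.82 (0.233), and the call also ended without medulloblastoma B6 (0.0604; range 7.20e-05 to 0.692). The oligodendrocyte precursor call ended without medulloblastoma B4 (0.205, mean 0.28 in place of 0.55) or C4 (0.159, mean 0.26; range 0.000138 to 0.674). The microglia call ended with the title prefix in the fit (0.819) and without medulloblastoma B4 (0.917, mean −0.06 in place of −0.34), C4 (0.0591), C5 (0.112) or C6 (0.0651). It also ended without normal brain B1 (0.0583), B2 (0.0711), C1 (0.348, mean −0.17) or C6 (0.141; range 5.10e-05 to 0.917); the mean was −0.63 without medulloblastoma B6 and −0.56 without normal brain C5. The cerebellum call ended without medulloblastoma B6 (0.898, mean 0.15 in place of −1.02, test downward), C1 (0.168), C2 (0.0732), C4 (0.115) or C5 (0.0593), and the mean was −2.18 without B4. It also ended without normal brain B1 (0.0789), B4 (0.0615), B6 (0.110), C5 (0.461, mean −0.32) or C6 (0.0686) and without the 3 normal brains rich in Gabra6 (0.0792; range 0.000671 to 0.898). The number of called lists was 2 without medulloblastoma C4 and 3 without medulloblastoma C5 or normal brain B1. The other 18 lists had adjusted p = 0.203 to 0.983, and the growth factor list, among others, differed in sign between median (0.07) and mean (−0.03). The same difference was not tested for glioma, which had 1 Rictor-null array.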

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

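The tests of tumour transcripts in normal brain C2, of Tmem267 in other tissues and of runs of neighbouring genes were chosen only after these results were seen, as was leaving out each array in the list tests; the regroupings of arrays and the background test were not.

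Among 96 groups and measures tested for a single distant array, 8 had one, where chance gives about 1 in 20, or 4.8. Of these 8, 7 lay in normal brain, in arrays C2, C5 and B2. The cell cycle score of Rictor-null normal brain C2 was 6.83 (4.84 to 5.34 in the other 4). Rictor-null C5 had a forebrain neuron score of 4.66 (7.05 to 7.62 in the others) and a cerebellum and Purkinje cell score of 10.1 (6.23 to 7.31). Heterozygous B2 had a granule lineage score of 7.41 (5.34 to 5.89), an astrocyte score of 10.5 (9.58 to 9.82), a cerebellum and Purkinje cell score of 8.82 (6.17 to 6.84) and a Rictor value of 8.63 on the log2 scale (at most 8.09 in the others). In glioma, heterozygous B2 had a p53 target score of 7.12 (6.60 to 6.68).

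For normal brain C2, medulloblastoma tissue in the piece is a candidate explanation: of the 100 genes most above normal brain in medulloblastoma, 88 were higher in C2 than in every other normal brain, against at most 4 for any other array. The share of tumour estimated from these genes was 12.6% in C2 and −2.65% to 1.53% in the others. A tumour array under a wrong label was argued against, since C2 correlated with the other normal brains (r = 0.971) more than with medulloblastomas (r = 0.828), a difference of 0.143. Whether the tissue was an early tumour or was carried over in dissection stays open, and no biological explanation was tested.

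The Rictor effects in medulloblastoma and normal brain differed, by a test of the difference itself, for the choroid plexus (adjusted p = 3.00e-06), oligodendrocyte precursor (0.00174), granule lineage (0.00416), microglia (0.0259) and cerebellum lists (0.0475). None passed with an estimated correlation (adjusted p = 0.394 to 0.862), and each lost its call without at least 1 array. The choroid plexus call ended without heterozygous medulloblastoma B4 (adjusted p = 0.520), the granule lineage call without normal brain C5 (0.233) and the cerebellum call without medulloblastoma B6 (0.898). The oligodendrocyte precursor (0.205) and microglia calls (0.917) ended without B4. No explanation of these differences was tested.

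In Rictor-null against p53-null-only medulloblastomas, 6 of the 56 groupings of the 8 tumours into sizes 5 and 3 gave at least the 1 gene of the real grouping, and the highest other count was 6, so chance is not excluded for the gene count. Of the 56 groupings 1, the real one, gave as many as its 12 called lists, and the highest other gave 10. This was 1 of several counts set against regroupings, without adjustment, so chance cannot be called excluded for it. None of the 12 passed with an estimated correlation, 10 lost their call without some single array, and 7 lists were called without A3, so the list result is fragile. A difference in mouse line background stays open as a candidate explanation for the gene differences: of 22 genes with an unadjusted p under 0.001, 77.3% had the same direction between heterozygous and p53-null-only normal brain. Random gene sets gave a median of 54.5% (central 95% 31.8% to 72.7%, one-sided permutation p = 0.0209 over 10000 draws of genes). With Rictor-null normal brain the share was again 77.3%, at the upper edge of the central 95% (36.4% to 77.3%, one-sided permutation p = 0.0353). Both rest on the 1 p53-null-only normal brain, A6, which shares its code, though not its title prefix, with 1 of the 3 p53-null-only medulloblastomas. Each also sets a Rictor-targeted genotype against one in which Rictor was not targeted. An effect of the Rictor alleles in both tissues would give the same agreement, so this test cannot tell it from background. For Tmem267, a sequence variant of the whole line under the probes was argued against as the sole cause, since the lower of the p53-null-only normal brain and glioma was 87.8, while the p53-null-only medulloblastomas had 2.1 to 14. Both arrays were low for their tissue: 1 of 10 other normal brains was lower than 87.8 (82.7 to 235.8), and none of 5 other gliomas was lower than 109.2 (129.3 to 208.4), so a smaller difference of the line stays open.

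Chance was excluded for the gene counts of the 3 tissue comparisons, where 1 of 100 groupings, the real one, gave as many: 8948 in medulloblastoma against normal brain (highest other 3717), 7510 in glioma against normal brain (5727) and 3959 in medulloblastoma against glioma (694). It was not excluded for their list counts: 18 of 100 groupings gave at least the 10 lists of medulloblastoma against normal brain (highest other 13), 55 gave the 7 of glioma against normal brain (13) and 24 gave the 8 of medulloblastoma against glioma (10). In normal brain the real count was 0 genes by limma (439 at an unadjusted p under 0.05), which any grouping reaches, so regrouping could not test it. Of the 100 groupings 38 gave at least its 9 lists (highest other 12), so chance was not excluded for the list count. The groupings were drawn without regard to the title prefix, so some of them mix a prefix difference into these counts. The grouping with 52 genes set the 5 YZ2 arrays (B6, B7, C1, C2 and C6) apart from the 5 YZ arrays, which points to a structure of the samples that follows the title prefix. With the prefix in the fit, the Rictor count in normal brain was 0 genes.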

How the results depend on the processing

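Leaving out the 3 normal brains rich in Gabra6, normal brain C2, glioma B1 or medulloblastoma C6, the prefix term and each left-out array in the list tests, and the block for the difference of both Rictor effects were chosen after seeing the data. No called named gene reversed direction in the alternatives run; genes named as not passing were not counted. Of 97, 100 and 80 called named genes in medulloblastoma against normal brain, glioma against normal brain and medulloblastoma against glioma, 26, 51 and 34 lost their call in at least 1 alternative; leaving out single arrays ended calls in 1, 10 and 10 genes. The median change of all genes shifted by at most 0.06 with quantile normalization. Leaving out 1 of the 2 heterozygous medulloblastomas leaves a lone array assumed to vary like other groups, and glioma C3 cannot be left out of its own comparison. The cause of the changes below was not tested, except that fewer arrays were used within a prefix or genotype and more tests were made with all probe sets.

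With all probe sets tested separately, 19513 were called in medulloblastoma against normal brain, 15523 in glioma against normal brain, 7291 in medulloblastoma against glioma, 3 in Rictor-null against p53-null-only medulloblastoma, 2 against heterozygous medulloblastoma and 6 in glioma. Within YZ the counts were 5439 for medulloblastoma against normal brain, 1873 against glioma and 0 for Rictor-null against p53-null-only medulloblastoma (limma; 605 genes at an unadjusted p under 0.05 with all arrays). Within YZ2 they were 3372 for glioma against normal brain, 1119 for medulloblastoma against glioma and 0 for Rictor-null against heterozygous medulloblastoma. Heterozygous arrays alone gave 5655 for medulloblastoma against normal brain and 1498 against glioma. Rictor-null against p53-null-only medulloblastoma gave 0 with heterozygous tumours pooled in, 0 with the title prefix as a fixed effect and 6 with all 28 arrays. Against heterozygous medulloblastoma, all 28 arrays, no pseudocount and the prefix each gave 0. In glioma no filter gave 6 and no pseudocount 24, of which 16.7% were higher (all 3 without this change). With an estimated correlation, 0 lists were called in each of the 8 comparisons. Without glioma B1, 9 lists were called in the glioma comparison, and with the prefix 4 lists in Rictor-null against heterozygous medulloblastoma.

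Leaving out each array in turn gave 0 to 3 genes in Rictor-null against p53-null-only medulloblastoma (3 without C4 or C6), 0 to 1 against heterozygous medulloblastoma, 0 to 1 in normal brain (1 without C6), 3 to 14 in glioma (14 without B7) and 0 to 4 for the difference of both Rictor effects (4 without B4). Called lists ranged from 7 to 14 in Rictor-null against p53-null-only medulloblastoma, 2 to 9 in glioma and 2 to 6 for the difference of both Rictor effects. In Rictor-null against heterozygous medulloblastoma the adjusted p ran from 5.55e-12 to 0.912 for choroid plexus (direction turned without B4), 1.49e-13 to 0.0959 for oligodendrocyte and 1.73e-05 to 0.612 for cerebellum genes (both turned without B6). The tissue comparisons ranged from 8532 to 9058, 6765 to 7580 and 2859 to 4250.

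With the code in the labels as a replicate block, 9248, 7806 and 3961 genes were called in the 3 tissue comparisons. When only codes with a single title prefix were used as blocks, the counts were 9128, 7849 and 3986. For the difference of both Rictor effects the replicate block gave 0 genes (limma; 264 at an unadjusted p under 0.05 without it). Of 11 tumour and normal pairs with the same code, 8 also shared the title prefix. All 11 agreed in Xist level, and 9 gave a correlation of their deviations (−0.04 to 0.32). Of these, 5 exceeded 0.1, 7 exceeded the mean with the other normal brains of the genotype and 5, including all 4 Rictor-null medulloblastomas among them, were highest for their own code. These are hints of shared animals from the data; since 4 pairs lay under 0.1, the codes were not treated as pairs.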

Other observations

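The tests of runs of neighbouring genes were all chosen only after the runs were seen.

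Tumours carried runs of neighbouring genes above the median of the other tumours of their type, among 8884 genes in the order of the RefSeq annotation of GRCm38.p6. In glioma B7, Arntl, Btbd10, Far1, Spon1, Rras2, Copb1 and Psma1 averaged 4.33 above the median of the other gliomas (log2). Rras2 encodes a RAS-family GTPase. In glioma B1 a run from Ifitm3 to Tmem80 lay 3.84 above that median, and in glioma B2 a run with Wdr11, Fgfr2, Ate1 and Tacc2 lay 1.94 above it. The run of glioma A4 lay 2.28 above, but over the same genes another glioma lay higher, at 3.07. Other gliomas reached 2.05 over the run of B7, 1.60 over that of B1 and 1.94 over that of C3. Glioma B3 reached 1.42 and did not pass (adjusted permutation p = 0.0639). Among medulloblastomas, C4 reached 3.09 (Tro, Maged2 and Fgd1 among the genes), C6 3.02, B6 2.63 with the cyclin gene Ccnd2, C5 2.19 with Mycn, and C2 2.10 with Gas1.

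The highest run lay on the chromosome of Rras2 in all 6 gliomas, including that of B3, in 1 of 10 medulloblastomas and in 4 of 12 normal brains. That chromosome held 6.28% of the ordered genes. It was picked because these runs lie on it, so a test of it would reuse the runs that chose it, and none is given. The median of its genes was −0.10 in medulloblastoma against glioma (other chromosomes −0.20 to 0.35) and 0.02 in glioma against normal brain (−0.22 to 0.17).

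Gain of DNA segments in the tumours is a hypothesis for these runs, which expression alone leaves open. A chance order of genes was argued against, since 15 of 16 tumours had a run at an adjusted permutation p under 0.05 against 1000 shuffled orders, and the runs of 10 tumours lay above every shuffled order. In normal brain 2 of 12 arrays, B4 and B7, met either mark. Shuffled orders cannot tell a gained segment from neighbouring genes that are regulated together. The run of medulloblastoma A3 holds the interferon response genes Ifit3 and Ifit1. A segment inherited by the animal was argued against where a normal brain shares the code, although the labels do not say that a code marks an animal: over the runs of 10 tumours such normal brains lay at most 0.29 above the others. For medulloblastoma C2 it cannot be told apart, since normal brain C2 lay 0.72 above the others and carried tumour transcripts. Normal brain tissue in the pieces was argued against in 13 of these 15 tumours, whose run lay above every normal brain by more than 1 SD of the normal brains. For medulloblastomas A5, whose run holds the choroid plexus gene Ttr, and A6 it cannot be told apart, since they lay 0.12 above the highest normal brain and −0.23 from it, within that SD.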
